A study of Caenorhabditis elegans with 10 samples.

How the data were processed

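Whole worms of the N2 strain were harvested at 10 times, every 2 h from 18 h to 36 h after hatched first-stage larvae were plated, with 1 library per time. Per the labels, worms were washed off the plates, monosomes were purified, and RNA of about 28-30 nucleotides was cut from a gel. Adapters were ligated with a small RNA kit and 4 barcoded primers were used; which library had which barcode is not given in the sources used here. The submitters' processing notes name Bowtie with no version. Genome build, annotation, counting rule and the handling of reads that fit several places are not given in the sources used here, so no coordinates are given.

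The authors deposited a table of raw counts of footprints per gene and library, in which no scaling had been applied. They also deposited normalized values, which were checked against the counts. The deposited normalized values are log2 values of the counts, scaled by the authors to the mean library total with 8 added, and the largest difference from that formula was 5e-05 log2. The count table holds 20182 genes, 1663 of them at 0 in all libraries. Of the identifiers, 19513 were found in the Ensembl 115 annotation, which gave the gene symbols, and 669 were not (1.13% of counts). Library totals were 27583634 (18 h), 19453343 (20 h), 24155948 (22 h), 16723638 (24 h), 33696423 (26 h), 23288789 (28 h), 17248486 (30 h), 22079848 (32 h), 28494156 (34 h) and 19766786 (36 h).

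Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes were tested when their CPM (counts scaled to a library of 1000000) passed the level of 10 counts in the median library in at least 3 libraries. Counts were scaled with TMM (factors 0.829 to 1.16). The edgeR model held an intercept, linear time and the cosine and sine of an 8 h period, 4 terms that leave 6 residual degrees of freedom. Dispersions and the quasi-likelihood fit were robust. The cosine and sine were tested together for oscillation and linear time alone for a trend, with p adjusted by the Benjamini-Hochberg method over all tested genes. A call needed an adjusted p under 0.05 and at least 1 log2, peak to trough or over the 18 h. Because each time has a single library, the error is the scatter around the curve, and a quick departure from a smooth curve counts as error.

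Genes were named by a fixed rule. In each 2 h of the cycle these are the 5 oscillating genes with the largest differences among those with a mean of at least 10 CPM, a gene-class name and changes of over 1 log2 repeated in direction 8 h later. The 8 largest rises and 8 largest falls with the same minimum level and a gene-class name, a fixed set of regulators and markers, and up to 3 called members and the most abundant member of each list complete it. The 32 gene lists, tissue and function markers named by symbol or family, hold 1011 tested genes, 27 of them in more than 1 list, and 34 listed names were not found. Their share oscillating was compared with 10000 random lists drawn within 20 bins of expression. Trends of lists were tested with limma camera on log2 CPM with a preset correlation of 0.01 and with an estimated correlation. For genes at 0 in some library, folds are bounds against 3 counts in that library. Library correlations used log2 CPM with a prior count of 2 after removing each gene's linear trend, with 100000 random orders of the time points.

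The fit was tested on simulated data, drawn from the real gene means, library sizes and dispersions, in which 200 genes with a mean of at least 50 counts oscillated and 200 others had a trend. Of genes changed by 1, 2, 4 and 6 log2, 24.0%, 94.0%, 100% and 100% were called as oscillating, with 6 false among 165 calls. For trends of the same sizes, 32.0%, 96.0%, 100% and 100% were called, with 4 false among 168 calls. The simulated changes were exact 8 h cosines or straight lines. The false calls therefore do not cover genes with another course, such as a single late rise. Alternatives fixed in advance were median-ratio factors, total counts alone, no filter, a mean of at least 50 counts, DESeq2, limma on log2 CPM or on the deposited values, periods of 7 h and 9 h, quadratic time, no trend or no cycle terms, no minimum size, thinning to the shallowest library and leaving out each library in turn. The newer quasi-likelihood method of edgeR and periods of 7.5 h and 8.5 h were added after the data had been seen. No library was left out.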

Results

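Ribosome footprints are the mRNA fragments that a translating ribosome shields from nuclease. They were sequenced from whole N2 worms, the standard wild-type strain of Caenorhabditis elegans, as larvae grew without interruption. Hatched first-stage larvae were put on bacteria, and 1 library was made every 2 h from 18 h to 36 h after plating. This gave 10 libraries and no replicate of any time point. Library totals ran from 16723638 counts (24 h) to 33696423 counts (26 h). No library was dominated by 1 gene: the most abundant of each held 1.02% to 1.43% of counts. The 10 genes most abundant on average over the libraries held 5.41% to 6.60%. The 100 most abundant of each library held 25.3% to 32.5%. Errors are standard errors of a curve fitted through the 10 libraries, and p-values measure scatter around that curve. Nothing in the labels says that the libraries came from separate cultures.

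The main comparison asked which genes had footprints that cycled with a period of 8 h. Only footprints were analysed, so changes in mRNA level and in translation cannot be told apart. Of 13958 genes tested, 3174 (22.7%) oscillated. The median fitted peak-to-trough difference was 2.42 log2 (5.34-fold), and 896 genes spanned at least 4 log2. Genes that build and remodel the cuticle, the collagen exoskeleton renewed at each moult, stood out. All 6 collagens of the annular furrows, 31 of 35 moulting genes and 23 of 24 genes of the pharyngeal cuticle oscillated. Footprints of dpy-7 (WBGene00001069), a furrow collagen, ran at 838 CPM (counts scaled to a library of 1000000) at 18 h, 9.93 CPM at 22 h, 712 CPM at 26 h, 15.2 CPM at 30 h and 627 CPM at 34 h. Genes were called by edgeR's quasi-likelihood F-test of the 8 h cosine and sine terms beside a linear time term. A call needed an adjusted p under 0.05 and a peak-to-trough difference of at least 1 log2. The period, the tests, the gene lists and the rule for naming genes were set before the data were examined. The period of 8 h was the length of the larval cycle already known for this study, so it was not an independent prediction. No gene passed at 7 h or 9 h (unadjusted p under 0.05 for 4415 and 3660 genes), and 3010 and 2222 passed at 7.5 h and 8.5 h.

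**Figure D1:**
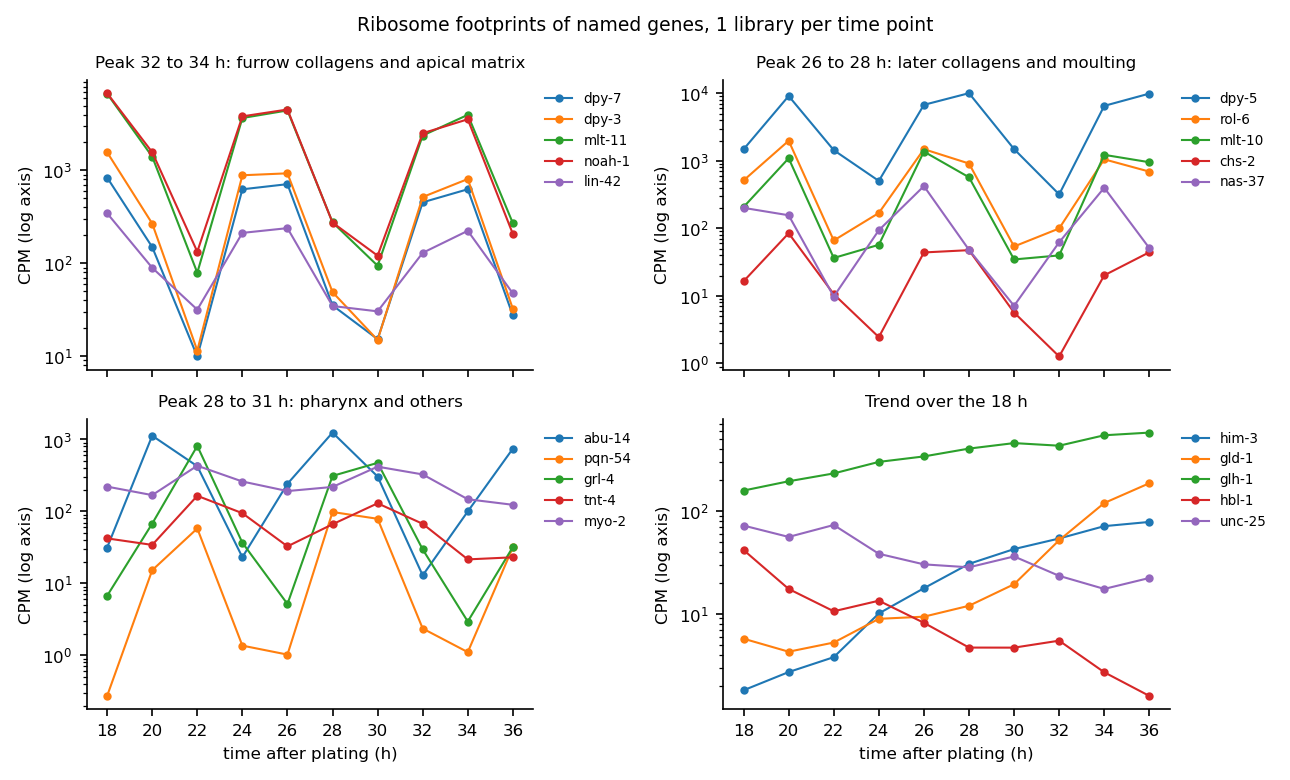
Footprint level in CPM, on a log axis, against time after plating in h for named genes. Each point is 1 library, and lines join the libraries in time order. At the upper left, mlt-11 stands at 6706, 4425 and 3967 CPM at 18 h, 26 h and 34 h, and at 79.2 and 94.2 CPM at 22 h and 30 h. At the lower right, him-3 goes from 1.80 CPM at 18 h to 53.9 CPM at 32 h.

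Peaks were spread around the whole cycle. Of the oscillating genes, 774 peaked between 26 h and 28 h, 779 between 28 h and 30 h, 860 between 30 h and 32 h and 761 between 32 h and 34 h. Each peak recurs every 8 h in the fit. Genes ranked below had a mean of at least 10 CPM, a gene-class name and changes over 1 log2 repeated in direction 8 h later. Under that level, nas-1 (WBGene00003520) differed by 9.14±1.66 log2 with a peak at 29.3 h and a mean of 2.61 CPM. Among the 5 largest differences with a peak from 26 h to 28 h were those of the hedgehog-related genes grl-5 (WBGene00001714) and grd-2 (WBGene00001691), at 7.04±0.76 and 6.85±0.81 log2. The lipase-related gene lips-9 (WBGene00010267) differed by 6.75±0.82 log2 and mam-2 (WBGene00008150) by 6.65±0.98 log2. The remaining gene, col-120 (WBGene00000694), stayed at or under 1.58 CPM through 32 h. It then reached 55.6 CPM at 34 h and 1603 CPM at 36 h, after a low peak of 35 counts at 28 h, so its large rise was seen once. From 28 h to 30 h the largest were dct-5 (WBGene00017218), abu-10 (WBGene00000033) and abu-8 (WBGene00000031), at 8.63±1.21, 8.37±0.87 and 8.24±0.84 log2. Also pqn-54 (WBGene00004139) and idpc-4 (WBGene00077691) differed by 8.07±0.74 and 8.06±0.61 log2. Levels of pqn-54 were 0.272, 57.9, 1.02, 78.9 and 1.10 CPM at 18 h, 22 h, 26 h, 30 h and 34 h. From 30 h to 32 h they were fipr-4 (WBGene00007541) and srlf-34 (WBGene00014173), at 7.94±0.97 and 7.04±0.90 log2. The degenerin-like del-6 (WBGene00011891), the P-glycoprotein gene pgp-5 (WBGene00003999) and col-103 (WBGene00000677) differed by 6.36±0.75, 6.17±0.71 and 5.95±0.76 log2. From 32 h to 34 h they were mltn-1 (WBGene00009311), dpy-8 (WBGene00001070) and col-149 (WBGene00000722), at 6.75±0.76, 6.72±0.74 and 6.71±0.59 log2. After these came atf-8 (WBGene00017535) at 6.56±0.60 log2 and dpy-3 (WBGene00001065) at 6.54±0.77 log2. The abu, pqn and fipr families hold similar copies. How reads that fit several genes were counted is not given in the sources used here, so values of single members are uncertain.

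**Figure D2:**
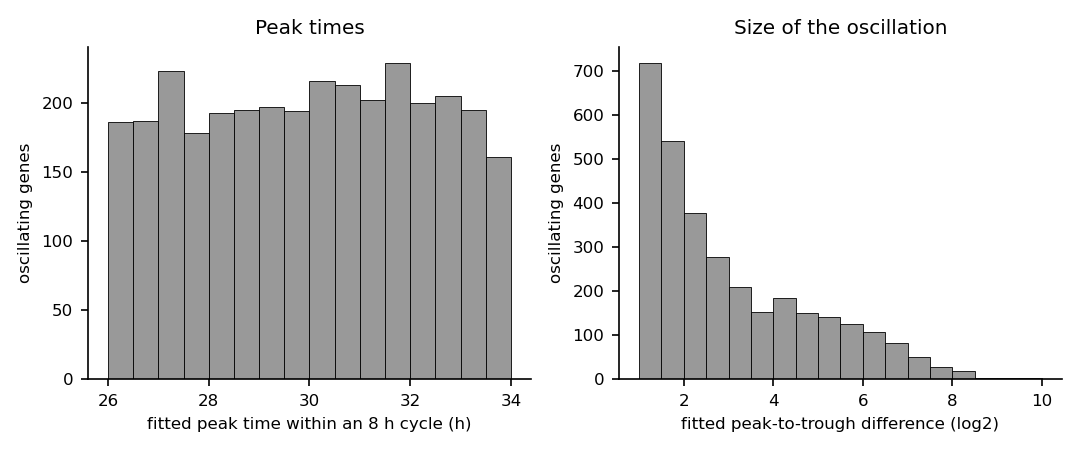
Left, the number of oscillating genes against their fitted peak time in h within an 8 h cycle, in bins of 0.5 h. Right, the number of oscillating genes against the fitted peak-to-trough difference in log2, in bins of 0.5 log2. Each 2 h of the cycle holds 24.0% to 27.1% of the 3174 genes.

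Gene lists described the cycle by tissue and function. The share oscillating in each list was set against 10000 random lists matched on expression in a permutation test, with p adjusted over 32 lists. The random lists hold genes drawn singly, so these p-values treat co-regulated members as independent. The correlation between members estimated by limma camera ran from -0.056 for reference genes to 0.991 for furrow collagens. All 6 furrow collagens oscillated (6 adjusted over the list alone, permutation adjusted p = 0.00151), against 1.48 on average in matched lists. Their median difference was 6.43 log2. Among the other body-shape collagens 10 of 13 oscillated (12 adjusted over the list alone, permutation adjusted p = 0.00128; 5 with a period of 8.5 h). Of these, dpy-5 (WBGene00001067), rol-6 (WBGene00004397) and lon-3 (WBGene00003057) differed by 4.75±0.54, 5.12±0.61 and 5.92±0.73 log2. Of the col genes 88 of 133 oscillated (101 adjusted over the list alone; 57 with a period of 8.5 h), against 30.5 in matched lists. The most abundant, col-73 (WBGene00000649), went from 206 CPM at 24 h to 5846 CPM at 28 h. A difference of 3.94±0.63 log2 was fitted for col-10 (WBGene00000599), a call lost with a period of 7.5 h. The adult collagen col-19 (WBGene00000608) was not called (4.41±1.73 log2) and stood at 8.26 CPM at 34 h and 179 CPM at 36 h. On the list of collagen-processing and cross-linking enzymes 14 of 19 oscillated (14 adjusted over the list alone). The astacin nas-7 (WBGene00003526) differed by 5.72±0.86 log2, and mlt-10 (WBGene00015646), a moulting gene that this list also holds, by 6.23±0.65 log2. The collagen prolyl hydroxylase subunit pdi-2 (WBGene00003963) differed by 1.86±0.22 log2. Of the moulting genes 31 of 35 oscillated (31 adjusted over the list alone). The fibrillin-related fbn-1 (WBGene00022816) and the lipocalin-related lpr-3 (WBGene00012261) differed by 6.33±0.58 and 6.14±0.66 log2. Others of this list, mlt-11 (WBGene00012186) and the apical matrix gene noah-1 (WBGene00016422), differed by 5.94±0.70 and 5.59±0.63 log2. Cuticlins had 22 of 34 oscillating (24 adjusted over the list alone), with cut-2 (WBGene00009983) at 5.93±0.77 log2. Hedgehog-related and patched-related genes had 55 of 72 (57 adjusted over the list alone), and grl-21 (WBGene00001730), grl-4 (WBGene00001713) and grl-16 (WBGene00001725) differed by 8.01±0.99, 7.42±0.80 and 6.82±0.83 log2. Astacin proteases had 22 of 26 (24 adjusted over the list alone), with nas-37 (WBGene00003553), a protease of ecdysis, at 5.26±0.59 log2. For these last 6 lists, from the col genes to the astacins, the permutation adjusted p of 0.000582 was the smallest that 10000 draws can give.

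Collagens with different places in the cuticle peaked at different times. The furrow collagens peaked together at 33.4 h (SD 0.0926 h, n = 6 genes). The oscillating members of the other body-shape collagens peaked at 26.8 h and every 8 h from there (SD 0.506 h, n = 10 genes), 1.46 h later. The difference had a two-sided exact permutation p of 0.000125 over 8008 regroupings of the 16 genes, which treats co-regulated genes as independent. Peaks lay at 33.5±0.141 h for dpy-8 and 33.4±0.138 h for dpy-2 (WBGene00001064), against 27.5±0.144 h for dpy-5 and 26.9±0.149 h for rol-6. Mean peaks were 28.6 h for col genes, 27.1 h for collagen enzymes, 26.1 h for moulting genes, 27.5 h for hedgehog-related genes and 28.6 h for astacins. Members of each list peaked at different times: the resultant length, 1 for a common peak time and 0 for an even spread, was 0.474, 0.344, 0.530, 0.463 and 0.416 in the same order. For the furrow collagens it was 0.998.

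In the pharynx, the feeding organ, most genes of the lining cycled. Of the pharyngeal cuticle genes 23 of 24 oscillated (23 adjusted over the list alone, permutation adjusted p = 0.000582). Their median difference was 6.82 log2 and their mean peak lay at 28.9 h (resultant length 0.632). The most abundant, abu-14 (WBGene00004174), ran from 1246 CPM at 28 h to 12.9 CPM at 32 h. The chitin synthase gene chs-2 (WBGene00000497) differed by 5.13±0.54 log2. Another member, abu-1 (WBGene00000024), had 0 counts at 18 h and 26 h and 5.46 CPM at 22 h, at least 53.5-fold higher than the level of 3 counts per library. Of the pharyngeal muscle genes 5 of 11 oscillated (5 adjusted over the list alone, permutation adjusted p = 0.162), against 2.38 on average in matched lists, with a mean peak at 30.6 h. The troponin genes tnt-4 (WBGene00006589) and tnc-2 (WBGene00006583) differed by 2.42±0.36 and 2.24±0.25 log2. A further member, marg-1 (WBGene00018538), differed by 4.45±0.77 log2 and the pharyngeal myosin myo-2 (WBGene00003514) by 1.45±0.26 log2. The myosin myo-1 (WBGene00002348) passed the adjusted p (0.0308) at 0.78±0.18 log2, under the size required.

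Regulators of moulting and of developmental timing gave a mixed picture. The worm relative of the circadian gene period, lin-42 (WBGene00018572), oscillated by 3.43±0.28 log2 with a peak at 33.4±0.105 h. The grainyhead transcription factor grh-1 (WBGene00001707) did so by 3.71±0.43 log2, with a peak at 34.0±0.146 h. Differences of 5.06±0.74, 4.03±0.62 and 2.12±0.21 log2 were found for bed-3 (WBGene00009133), nhr-74 (WBGene00003664) and myrf-1 (WBGene00004134). The nuclear receptor nhr-23 (WBGene00003622) missed the threshold at 2.52±0.65 log2 (edgeR adjusted p = 0.0586). So did nhr-25 (WBGene00003623) at 1.91±0.73 log2 (adjusted p = 0.191) and nhr-85 (WBGene00003675) at 2.23±0.60 log2 (adjusted p = 0.0721). Between their lowest and highest libraries nhr-23, nhr-25 and nhr-85 differed 10.8-fold, 12.7-fold and 26.0-fold, any trend included. A missed call is therefore not a sign of a small change. The zinc finger gene blmp-1 (WBGene00003847) passed the adjusted p (0.0304) at 0.89±0.21 log2, under the size required. Of the moulting-clock transcription factors 8 of 20 oscillated (9 adjusted over the list alone, permutation adjusted p = 0.128). Of the heterochronic genes, which time larval stages, 4 of 19 did (4 adjusted over the list alone, permutation adjusted p = 1.00), and of the epidermis and seam genes 9 of 23 (9 adjusted over the list alone, permutation adjusted p = 0.138). In the last list mua-3 (WBGene00003482), which anchors the epidermis, differed by 2.61±0.37 log2 and bro-1 (WBGene00000272) by 2.80±0.47 log2.

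Intestinal and defence genes cycled in part. Of the intestine genes 15 of 36 oscillated (15 adjusted over the list alone, permutation adjusted p = 0.0298), with a median of 1.79 log2. The cathepsin B-like cpr-6 (WBGene00000786) differed by 3.35±0.31 log2 with a peak at 26.9±0.115 h, and cpr-4 (WBGene00000784) by 2.97±0.26 log2 with a peak at 32.5±0.112 h. The aquaporin aqp-8 (WBGene00000176) differed by 3.06±0.35 log2. The GATA factor elt-2 (WBGene00001250) and the protease asp-1 (WBGene00000214), the most abundant, were not called (0.71±0.26 and 0.69±0.22 log2). Of the antimicrobial and epidermal innate immunity genes 15 of 27 oscillated (15 adjusted over the list alone, permutation adjusted p = 0.000582). The peptide genes nlp-25 (WBGene00003763) and nlp-26 (WBGene00003764) differed by 5.94±0.47 and 5.63±0.85 log2, and nlp-33 (WBGene00003771), the most abundant, by 2.69±0.25 log2. A called member, abf-4 (WBGene00000015), never exceeded 2.11 CPM and was lost without the 22 h library. Starvation and fasting genes had 7 of 24 oscillating (7 adjusted over the list alone, permutation adjusted p = 0.697). They include cpt-4 (WBGene00019644), fat-5 (WBGene00001397) and dod-3 (WBGene00016052), at 3.61±0.34, 3.12±0.44 and 2.90±0.44 log2. Oxidative and xenobiotic stress genes had 7 of 22 (7 adjusted over the list alone, permutation adjusted p = 0.513), with ugt-11 (WBGene00020593), ugt-13 (WBGene00019232) and cyp-35A5 (WBGene00019473) at 4.35±0.56, 3.54±0.45 and 2.86±0.37 log2. Heat shock and unfolded protein genes had 4 of 16 (4 adjusted over the list alone, permutation adjusted p = 1.00; 2 without the library at 22 h, 24 h, 26 h, 28 h, 30 h or 36 h), with hsp-43 (WBGene00002024) at 2.69±0.41 log2. The most abundant members of these 3 lists, dct-16 (WBGene00012615), prdx-2 (WBGene00006434) and hsp-1 (WBGene00002005), were not called (0.54±0.17, 0.43±0.09 and 0.19±0.11 log2).

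Several tissues and housekeeping complexes held fewer oscillating genes than matched lists. None of 37 body-wall muscle genes was called by edgeR (0 adjusted over the list alone, permutation adjusted p = 0.000582) or DESeq2, with an unadjusted p under 0.05 for 14. Of these genes, 12 passed the adjusted p at a size under 1 log2. Their median difference was 0.45 log2 and their mean peak lay at 29.3 h (resultant length 0.728). Levels of the muscle myosin unc-54 (WBGene00006789) stayed between 5413 CPM and 9224 CPM. None of 80 ribosomal protein genes was called by either tool (0 adjusted over the list alone, permutation adjusted p = 0.000582; unadjusted p under 0.05 for 22). The same held for 30 translation factors (0 adjusted over the list alone, permutation adjusted p = 0.00151; unadjusted p under 0.05 for 8). It held for 33 meiosis and synapsis genes (0 adjusted over the list alone, permutation adjusted p = 0.00128; unadjusted p under 0.05 for 2). The proteasome also had 0 of 33 by both tools (0 adjusted over the list alone, permutation adjusted p = 0.000985). Yet 30 of its genes passed the adjusted p at a size under 1 log2. Their median difference was 0.52 log2 and their mean peak lay at 26.4 h (resultant length 0.987). The most abundant, rpn-1 (WBGene00004458), differed by 0.44±0.09 log2. Of all footprints the proteasome list held 0.824%, 0.642%, 0.809%, 0.730% and 0.816% at 18 h, 22 h, 26 h, 30 h and 34 h. TMM factors were 1.16 and 1.11 at 22 h and 30 h, against 1.07, 0.989 and 0.858 at 18 h, 26 h and 34 h. The size of this small cycle therefore depends in part on the scaling. Neurons had 1 of 38 oscillating (0 adjusted over the list alone, permutation adjusted p = 0.00356; 0 without the library at 20 h, 22 h, 24 h, 28 h, 32 h, 34 h or 36 h) and the germline list 1 of 48 (1 adjusted over the list alone, permutation adjusted p = 0.000985). Cell cycle genes had 3 of 45 (1 adjusted over the list alone, permutation adjusted p = 0.0246; 1 without the library at 30 h or 34 h). With no minimum size, 9 neuronal, 4 germline and 10 cell cycle genes passed the adjusted p. So did 3 ribosomal protein, 3 translation factor and 1 meiosis gene. The most abundant cell cycle gene, the ribonucleotide reductase gene rnr-2 (WBGene00004392), oscillated by 1.45±0.23 log2 with a peak at 27.2±0.198 h.

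Other lists did not pass the test against matched lists or rose once. Vulva, anchor cell and somatic gonad genes had 3 of 31 oscillating, against 7.28 in matched lists (2 adjusted over the list alone, permutation adjusted p = 0.124; 5 with total counts alone, 1 without the library at 22 h and 5 without the library at 34 h). Oocyte and eggshell genes had 2 of 16, against 3.67 (2 adjusted over the list alone, permutation adjusted p = 0.585; 1 with total counts alone, 1 without the library at 18 h, 20 h or 28 h). Yolk proteins had 0 of 3 and reference genes 0 of 12 by edgeR and DESeq2, against 0.584 and 2.87 in matched lists (0 adjusted over the list alone for both, permutation adjusted p = 1.00 and 0.103; unadjusted p under 0.05 for 0 and 4). The reference genes gpd-3 (WBGene00001685) and vha-13 (WBGene00013025) had differences of 0.19±0.09 and 0.53±0.09 log2. Of the major sperm protein genes 16 of 24 met the oscillation criteria (20 adjusted over the list alone, permutation adjusted p = 0.000582). These genes stood under 1 CPM through 28 h and then rose once. DESeq2 called 1, a quadratic time term left 8, and the count was 1 to 9 without the library at 22 h, 30 h, 32 h, 34 h or 36 h. Other sperm genes had 6 of 51 (4 adjusted over the list alone, permutation adjusted p = 0.103), 2 by DESeq2 and 2 without the library at 22 h or 36 h.

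**Figure D3:**
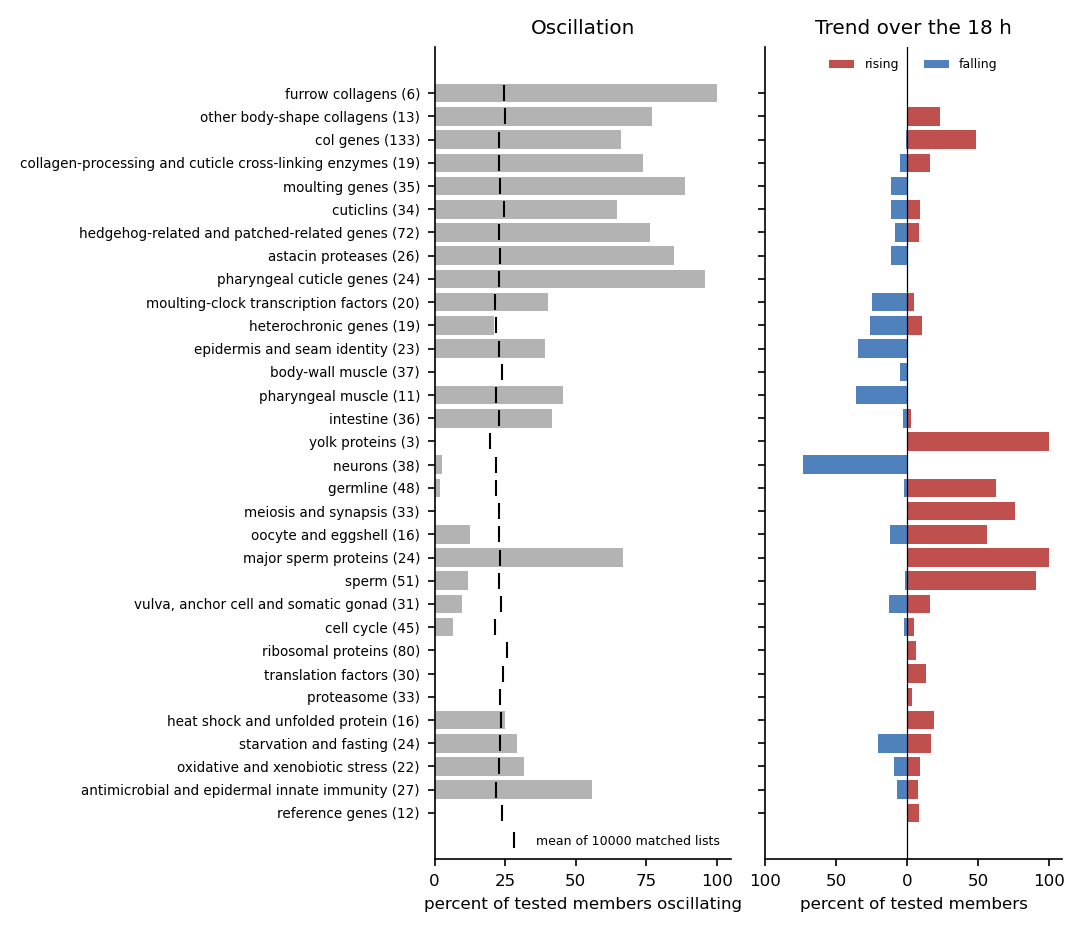
Left, the percent of tested members of each gene list (their number in brackets) that oscillated, as bars, with the mean of 10000 expression-matched lists as ticks. Right, the percent that rose (red, to the right) or fell (blue, to the left) over the 18 h. Cuticle and moulting lists lie far above their ticks at the left. At the right, 30 of 48 germline genes rose and 28 of 38 neuronal genes fell.

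Whole libraries repeated in part. After each gene's linear trend was removed, libraries 8 h apart had a mean Pearson r across genes of 0.329 (6 pairs, from -0.0646 to 0.771). Those 4 h apart had -0.618 (8 pairs), those 12 h apart -0.660 (4 pairs) and those 16 h apart 0.787 (2 pairs). The pairs 16 h apart are 18 h with 34 h and 20 h with 36 h, the ends of the course. The mean r at 8 h exceeded that at 4 h by 0.947 (two-sided permutation p = 0.00334, 100000 orders of the time points). With only the gene means removed the difference was 0.283 (permutation p = 0.341). Changes over 4 h, taken with no trend removed, recurred 8 h later in other libraries across 13958 genes. They are given without a p-value because genes are not replicates. The change from 18 h to 22 h correlated with that from 26 h to 30 h at r = 0.701. The change from 20 h to 24 h did so with that from 28 h to 32 h at r = 0.637. For 22 h to 26 h with 30 h to 34 h r was 0.725, and for 24 h to 28 h with 32 h to 36 h it was 0.737. Of the genes that changed by over 1 log2 in the earlier interval, 89.7% to 93.8% moved the same way in the later one. A gene that keeps rising or falling also adds to these correlations and shares. Principal component 1 held 59.7% of the variance and separated late from early libraries. Components 2 and 3, with 17.02% and 15.8%, turned with the cycle. Among periods from 5 h to 14 h, 8 h gave the most oscillating genes and explained 65.1% of the detrended variance, against 63.99% at 7.5 h.

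**Figure D4:**
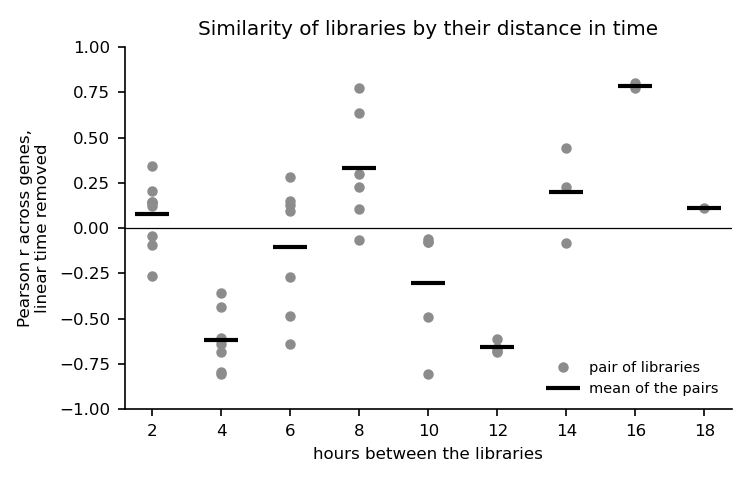
Pearson r across genes between pairs of libraries, after removing each gene's linear time trend, against the h between the libraries. Grey points are pairs and black bars their means. The means lie at -0.618 for 4 h, 0.329 for 8 h, -0.660 for 12 h and 0.787 for 16 h.

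Apart from the cycle, footprints of many genes moved in one direction from 18 h to 36 h. Over these 18 h, 2186 genes (15.7%) rose and 1508 (10.8%) fell, 436 and 326 of them oscillating too. Most germline, meiosis and sperm genes rose (30 of 48, 25 of 33 and 46 of 51), and so did all 24 major sperm protein genes. Most neuronal genes fell (28 of 38), and 64 of 133 col genes rose. Calls came from the same edgeR fit and needed a change of at least 1 log2 over the 18 h. Changes are relative to the other genes. The median gene changed by -0.02 log2 under the scaling used, by -0.33 log2 with total counts alone and by 0.04 log2 with median-ratio factors. Rising genes made up 59.2%, 44.4% and 62.1% of these calls in the same order.

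Footprints of most sperm genes rose during the course. The major sperm protein genes encode the cytoskeletal protein of worm sperm. They held 0.00237% of all footprints at 30 h (95% Wilson interval 0.00215% to 0.00261%) and 0.146% at 36 h (0.144% to 0.147%). These intervals cover counting error within 1 library only and do not test the change. When adjusted over the list alone, 24 of 24 rose. The list had a limma camera adjusted p of 5.08e-10 with a preset correlation of 0.01, and adjusted p = 0.532 with an estimated correlation. The most abundant, msp-64 (WBGene00003457), had 0 counts from 18 h to 24 h and 3.07, 29.5, 154 and 274 CPM from 30 h to 36 h. The last value is at least 1679.5-fold higher than the level of 3 counts per library. The msp copies are nearly identical, so single members are uncertain. Other genes with the largest rises, of those with a gene-class name and a mean of at least 10 CPM, against the same floor, were ssq-2 (WBGene00006051) and ssq-1 (WBGene00006050), at least 2912-fold and at least 2179.9-fold higher. For msp-45 (WBGene00003438) the rise was at least 499.8-fold, and msd-2 (WBGene00009682) had 0 counts through 26 h and 82.3 CPM at 36 h. The eggshell gene perm-2 (WBGene00016636) and ule-4 (WBGene00007458) were at least 719.7-fold and at least 1618-fold higher. A collagen gene, col-63 (WBGene00000639), rose from 0.0680 CPM at 18 h to 3469.6 CPM at 36 h. In the sperm list 46 of 51 genes rose adjusted over the list alone and 1 fell (camera adjusted p = 2.59e-13 preset, adjusted p = 0.524 with an estimated correlation). A member, spe-18 (WBGene00009308), went from 0.630 CPM at 26 h to 264 CPM at 36 h. All 3 yolk protein genes rose (3 adjusted over the list alone; camera adjusted p = 0.0653 preset, adjusted p = 0.584 with an estimated correlation). From 30 h to 36 h vit-2 (WBGene00006926) went from 0.833 to 244 CPM, vit-6 (WBGene00006930) from 0.208 to 246 CPM and vit-1 (WBGene00006925) from 5.41 to 139.6 CPM. Oocyte and eggshell genes had 9 of 16 rising and 2 falling (9 and 2 adjusted over the list alone; camera adjusted p = 0.0301 preset, adjusted p = 0.524 with an estimated correlation). The falling count was 1 without the library at 18 h, 20 h, 22 h, 26 h, 32 h or 34 h. A rising member, cpg-3 (WBGene00011063), stood at 0.409 CPM at 18 h and 84.9 CPM at 36 h.

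Most germline and meiosis genes rose over the course. Of the germline genes 30 of 48 rose (30 adjusted over the list alone) and 1 fell, with a median change of 1.65 log2. Of the 32 lists only this one was called by camera both with the preset correlation (adjusted p = 3.35e-12) and with an estimated one (adjusted p = 0.00820). The Vasa-like helicase glh-1 (WBGene00001598) rose by 1.84±0.15 log2 and the translational regulator gld-1 (WBGene00001595) by 5.48±0.60 log2. Levels of cpb-1 (WBGene00000770) went from 0.490 CPM at 24 h to 18.5 CPM at 32 h and stood at 12.2 CPM at 36 h. The receptor gene glp-1 (WBGene00001609) was not called (0.30±0.34 log2). The germline member that fell was lin-41 (WBGene00003026), also a heterochronic gene, at -3.05±1.07 log2. It stood at 76.0 CPM at 22 h, 5.99 CPM at 30 h and 25.08 CPM at 36 h. Its call was lost without the library at 18 h, 20 h, 22 h, 26 h, 32 h or 34 h. Of the meiosis and synapsis genes 25 of 33 rose (25 adjusted over the list alone; camera adjusted p = 1.41e-15 preset, adjusted p = 0.135 with an estimated correlation). The chromosome axis genes him-3 (WBGene00001862) and htp-1 (WBGene00002032) rose by 5.86±0.46 and 5.10±0.60 log2. The synaptonemal complex gene syp-4 (WBGene00019247) rose by 5.22±0.57 log2. The translation factors iff-1 (WBGene00002064) and ife-1 (WBGene00002059) rose by 2.96±0.17 and 1.87±0.13 log2, and the ribosomal protein gene rpl-11.1 (WBGene00004422) by 2.96±0.14 log2. The proteasome gene rpn-6.2 (WBGene00010309) went from 0.238 CPM at 18 h to 49.3 CPM at 36 h.

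Many col genes rose, while most other collagens on the lists did not. Of the col genes 64 of 133 rose (66 adjusted over the list alone; camera adjusted p = 5.37e-09 preset, adjusted p = 0.102 with an estimated correlation; 35 with no cycle terms), and 1 fell (2 with total counts alone or by DESeq2, 3 with quadratic time, 2 without the library at 22 h). Their share of footprints was 3.07% at 20 h, 6.44% at 28 h and 9.87% at 36 h, the same point of 3 cycles. The adult cuticle collagens bli-1 (WBGene00000251) and bli-2 (WBGene00000252) stood at 4.42 and 2.91 CPM at 30 h, 5554 and 3386 CPM at 34 h and 768 and 756 CPM at 36 h, and both rose over the course. Of the other body-shape collagens 3 of 13 rose (2 adjusted over the list alone, camera adjusted p = 0.0672). No furrow collagen rose or fell by edgeR (0 adjusted over the list alone, camera adjusted p = 0.214; unadjusted p under 0.05 for 2). With total counts alone 2 fell, as did 2 by DESeq2 and 2 without the library at 22 h. The heterochronic genes lin-29 (WBGene00003015) and mab-10 (WBGene00003107) act at the switch to the adult and rose by 5.26±0.59 and 7.30±0.53 log2. They went from 1.02 and 0.272 CPM at 18 h to 32.2 and 25.4 CPM at 34 h, and were lower again at 13.3 and 9.17 CPM at 36 h. The latter is called oscillating too.

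Some genes of larval timing and of the epidermis fell. The heterochronic transcription factor hbl-1 (WBGene00001824) changed by -3.90±0.28 log2, from 41.6 CPM at 18 h to 1.59 CPM at 36 h. The nuclear receptor daf-12 (WBGene00000908) changed by -3.80±0.35 log2 and lin-14 (WBGene00003003) by -1.70±0.21 log2, whereas lin-28 (WBGene00003014) was not called (-0.40±0.29 log2). Of the heterochronic genes 5 of 19 fell and 2 rose (5 and 2 adjusted over the list alone; camera adjusted p = 0.00998 preset, adjusted p = 0.102 with an estimated correlation). The number falling was 9 with total counts alone, 3 with no cycle terms and 3 without the library at 34 h. Among the other genes with the largest falls, of those with a gene-class name and a mean of at least 10 CPM, the tubulin gene tba-8 (WBGene00006534) went from 101 CPM at 18 h to 0.0610 CPM at 36 h. Changes for nas-3 (WBGene00003522) and hmbx-1 (WBGene00018786) were -5.08±0.39 and -4.30±0.88 log2, the latter call lost without the 36 h library. The insulin-like ins-5 (WBGene00002088) and the lectin-like clec-42 (WBGene00008891) changed by -3.73±0.33 and -3.64±0.43 log2. The cytochrome P450 gene daf-9 (WBGene00000905), of dafachronic acid synthesis, changed by -3.12±0.61 log2. Of the moulting-clock transcription factors 5 of 20 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.00459 preset, adjusted p = 0.102 with an estimated correlation). The number falling was 10 with total counts alone, 2 with no cycle terms, and 2 rose without the library at 18 h. Of the epidermis and seam genes 8 of 23 fell (8 adjusted over the list alone; camera adjusted p = 0.00459 preset, adjusted p = 0.102 with an estimated correlation). Of these, ceh-16 (WBGene00000439) changed by -5.06±0.62 log2 and bro-1 by -3.72±0.54 log2.

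Most of the neuronal genes tested fell. Of the neuronal genes 28 of 38 fell (29 adjusted over the list alone; camera adjusted p = 7.25e-16 preset, adjusted p = 0.102 with an estimated correlation), and 0 rose by edgeR or DESeq2. The median change was -1.34 log2, -1.66 with total counts alone and -1.28 with median-ratio factors. The GABA genes unc-25 (WBGene00006762) and unc-46 (WBGene00006782) changed by -1.98±0.22 and -2.49±0.24 log2, and unc-47 (WBGene00006783) went from 4.56 CPM at 18 h to 1.10 CPM at 36 h. The neuropeptide-processing gene egl-3 (WBGene00001172), the most abundant member, changed by -1.04±0.13 log2. Its call was lost with median-ratio factors, with DESeq2 and without the 18 h or 22 h library. Of the body-wall muscle genes 2 of 37 fell (2 adjusted over the list alone, camera adjusted p = 0.517). The troponin gene tni-1 (WBGene00006584) changed by -1.15±0.09 log2 and hlh-1 (WBGene00001948) by -1.05±0.12 log2, the latter call lost with median-ratio factors, with DESeq2 and without the 32 h library. Of the pharyngeal muscle genes 4 of 11 fell (4 adjusted over the list alone; camera adjusted p = 0.0215 preset, adjusted p = 0.584 with an estimated correlation; 2 without the library at 36 h).

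Ribosomal, translation and proteasome lists had few trend calls, and many of their genes changed by less than the size required. Ribosomal protein genes had 5 of 80 rising (5 adjusted over the list alone; camera adjusted p = 1.69e-11 preset, adjusted p = 0.640 with an estimated correlation; 9 with median-ratio factors or by DESeq2, 8 to 24 without the library at 20 h, 30 h or 36 h). Their median change was 0.72 log2, and the most abundant, rla-0 (WBGene00004408), passed the adjusted p (0.00182) at 0.74±0.12 log2, under the size required. Unadjusted p was under 0.05 for 74 of these genes, for 14 of 30 translation factors and for 26 of 33 proteasome genes. Translation factors had 4 of 30 rising (4 adjusted over the list alone, camera adjusted p = 0.0541), and eef-1A.1 (WBGene00001168) passed the adjusted p (0.00255) at 0.70±0.13 log2, under the size required. The proteasome had 1 of 33 rising (1 adjusted over the list alone; camera adjusted p = 5.49e-06 preset, adjusted p = 0.640 with an estimated correlation). Heat shock and unfolded protein genes had 3 of 16 rising (3 adjusted over the list alone; camera adjusted p = 0.0301 preset, adjusted p = 0.415 with an estimated correlation). Of these, hsp-70 (WBGene00002026) changed by 3.48±0.41 log2 and sip-1 (WBGene00004798) by 2.83±0.51 log2. Cell cycle genes had 2 rising and 1 falling (2 and 1 adjusted over the list alone, camera adjusted p = 0.465). The cyclin gene cyb-1 (WBGene00000865) changed by 1.62±0.20 log2 and cdk-4 (WBGene00000406) by -1.39±0.33 log2, the latter call lost without the 36 h library. Rising members were 1 with total counts alone, and falling members were 3 with total counts alone, 2 with quadratic time, 0 with no cycle terms, 0 without the library at 36 h and 3 without the library at 18 h. The reference genes had 1 of 12 rising (0 adjusted over the list alone, camera adjusted p = 0.897). This was act-1 (WBGene00000063), at 3.37 CPM at 18 h and 6.05 CPM at 36 h. Its near-identical actin copies leave this level uncertain, and the call was lost with total counts alone and without the library at 18 h, 20 h, 22 h, 24 h, 26 h, 28 h, 30 h, 32 h or 36 h. Trends of gpd-3, unc-54 and elt-2 were not called (0.03±0.10, 0.10±0.17 and -0.36±0.29 log2).

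The remaining lists had fewer trend calls, or calls in both directions, and the counts of several depend on the scaling and the model. Vulva, anchor cell and somatic gonad genes had 5 rising and 4 falling (5 and 5 adjusted over the list alone, camera adjusted p = 0.723; falling, 9 with total counts alone). Of these, the gap junction gene inx-8 (WBGene00002130) changed by 5.36±0.64 log2 and lin-11 (WBGene00003000) by 2.63±0.59 log2. Intestine genes had 1 rising and 1 falling (1 and 1 adjusted over the list alone, camera adjusted p = 0.955; rising, 0 with no cycle terms, 2 without the library at 20 h; falling, 3 with total counts alone, 2 with quadratic time, 2 without the library at 20 h, 22 h, 28 h or 30 h). Moulting genes had 0 rising and 4 falling (0 and 2 adjusted over the list alone, camera adjusted p = 0.223; falling, 7 with total counts alone, 0 with no cycle terms, 2 without the library at 34 h or 36 h). Cuticlins had 3 rising and 4 falling (3 and 3 adjusted over the list alone, camera adjusted p = 0.517; falling, 7 with total counts alone, 2 with no cycle terms). Hedgehog-related and patched-related genes had 6 rising and 6 falling (4 and 3 adjusted over the list alone, camera adjusted p = 0.903; rising, 3 with no cycle terms; falling, 11 with total counts alone, 1 with no cycle terms, 3 without the library at 34 h). Astacin proteases had 0 rising and 3 falling (0 and 2 adjusted over the list alone, camera adjusted p = 0.353; rising, 1 without the library at 36 h; falling, 5 with total counts alone, 8 without the library at 18 h). Collagen-processing enzymes had 3 rising and 1 falling (3 and 0 adjusted over the list alone, camera adjusted p = 0.484; rising, 1 without the library at 36 h; falling, 0 with median-ratio factors, by DESeq2, with quadratic time or with no cycle terms, 0 without the library at 22 h, 26 h, 28 h, 30 h, 32 h, 34 h or 36 h and 2 without the library at 18 h). Pharyngeal cuticle genes had 0 rising and 0 falling (0 and 0 adjusted over the list alone, camera adjusted p = 0.897; rising, 1 with median-ratio factors or by DESeq2, 2 with quadratic time, 2 without the library at 28 h or 36 h; falling, 1 with total counts alone, 2 by DESeq2, 2 to 3 without the library at 18 h or 20 h). Starvation and fasting genes had 4 rising and 5 falling (4 and 5 adjusted over the list alone, camera adjusted p = 0.223; rising, 2 with total counts alone; falling, 3 without the library at 20 h). Oxidative and xenobiotic stress genes had 2 rising and 2 falling (2 and 1 adjusted over the list alone, camera adjusted p = 0.650; rising, 1 with no cycle terms, 1 without the library at 36 h; falling, 1 with median-ratio factors or with quadratic time, 0 with no cycle terms, 0 to 1 without the library at 18 h, 20 h, 22 h, 28 h, 32 h, 34 h or 36 h). Antimicrobial and epidermal innate immunity genes had 2 rising and 2 falling (2 and 1 adjusted over the list alone, camera adjusted p = 0.650; rising, 1 with total counts alone, 0 with no cycle terms, 1 without the library at 18 h, 20 h or 34 h; falling, 1 with quadratic time or with no cycle terms, 1 without the library at 18 h, 22 h, 34 h or 36 h).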

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

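The periods of 7.5 h and 8.5 h and the newer edgeR method were chosen after the data had been seen. Of 118 values recomputed for the main comparisons, 107 kept their direction and side of the threshold or, where they had no test of their own, stayed within 1.5 times for counts of genes and within 0.1 for correlations. The limit of 0.1 was an arbitrary choice, as these correlations have no spread between replicates. The difference in r by Spearman correlation was counted among them on its direction alone, since its p was not computed. With total counts alone 2434 genes fell, and 2344 fell on the deposited values with a pseudocount of 1, both scaled to library totals. With a mean of at least 50 counts 1313 rose and 940 fell, with fewer genes tested. At an adjusted p alone 4796 oscillated and 2635 fell, with no minimum size. Oscillating genes were 0 with a period of 7 h and 0 with 9 h. These periods explained 51.2% and 48.4% of the detrended variance, against 65.1% at 8 h. With no time trend in the model 2062 genes oscillated, and a trend then counts as error. The causes were not tested further. The difference in r between 8 h and 4 h was 0.283 with no detrending and no longer past the threshold; without detrending the trend stays in the values. By Spearman correlation the change from 18 h to 22 h followed that from 26 h to 30 h at 0.5999; the cause was not tested.

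Leaving out 1 library gave 2469 to 3127 oscillating, 2030 to 2197 rising and 1272 to 1570 falling genes, a difference in r of 0.757 to 1.11 and a collagen delay of 1.21 to 1.67 h. DESeq2 called 3173 oscillating genes, 2925 of them shared, and quadratic time 2865, 2668 shared. The collagen delay has no value at 7 h and 9 h, where no gene oscillated. Among values of single genes and lists, 5946 stayed, 345 moved and 435 lost their call, and none reversed. Thinning every library to the depth of the shallowest left 3092 oscillating genes.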

Other observations

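The comparison of gene families and the test of how peaks spread over the cycle were chosen after the results had been seen. Families that share a symbol stem were set against all other tested genes with Fisher's exact test, p adjusted over 184 families, which treats family members as independent. Besides the lists, oscillating genes were frequent among the UDP-glucuronosyltransferase genes ugt (38 of 60, exact adjusted p = 1.71e-09), the families fipr (12 of 14, exact adjusted p = 2.19e-05) and phat (8 of 8, exact adjusted p = 0.000101). The same held for the transthyretin-related ttr genes (22 of 49, exact adjusted p = 0.00632) and the glutathione transferase genes gst (17 of 35, exact adjusted p = 0.00625). Among the nuclear receptor genes nhr 36 of 185 fell, more than the 10.8% of all tested genes (exact adjusted p = 0.00605). Only 3 of 185 rose, fewer than the 15.7% of all tested genes (exact adjusted p = 1.24e-08). Neuropeptide genes of the families flp and nlp had 18 of 30 and 23 of 63 falling (exact adjusted p = 1.63e-08 and 2e-06), and mec genes of touch neurons 11 of 14 (exact adjusted p = 3.71e-07).

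The cycle of 8 h might come from the libraries rather than the worms, and 4 explanations of that kind were examined. Of 100 orders of the time points, 1, the real one, gave as many oscillating genes, and the highest of the others gave 1286. This makes a chance order unlikely, but 100 orders cannot exclude it. Shuffling also breaks any smooth course, so a smooth change without a cycle was not tested. The 4 barcodes, if used in time order, would recur every 8 h. Of the repeated variance of 4305 genes 4.63% alternated from library to library, against 33.3% for a pattern with no smooth course. The 33.3% assumes effects that differ at random from gene to gene, so a barcode effect shared by many genes stays open. Depth was highest at 18 h, 26 h and 34 h, and 92.2% of the oscillating genes were called again after thinning to the shallowest library. Few calls therefore hang on the number of counts. Thinning leaves each gene's expected share of a library unchanged, so it cannot test a difference in preparation that goes with depth. The busiest 2 h of the cycle held 27.1% of the peaks. The TMM scaling balances rises and falls within each library, so this spread cannot decide on a single scaling error. A rhythm of the growing worms may underlie the cycle, a hypothesis that stays open since no group of the design tests it and each time has 1 library.

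The rise of 2186 genes may come from the order of the libraries or their scaling. In 1 of 100 orders, the real one, as many genes rose, and the highest of the others gave 1194 (1011 for the 1508 falling genes, as many in 1 of 100). This makes a chance order unlikely, but 100 orders cannot exclude it. With total counts alone 1940 genes rose, within 1.5 times. Growth of the germ line relative to other tissues is a possible explanation for part of the rise. No measurement here tests it, since whole worms were used and no cell numbers are given. Genes outside the germline lists rose too, among them 64 of 133 col genes.

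Worms of a culture may drift apart in time, which would flatten the cycle in later libraries. Over 1357 oscillating genes with a mean of at least 10 CPM and no trend call, the median range was 2.46 log2 in the first 5 libraries and 2.42 log2 in the last 5. The median difference of last minus first was 0.0555 log2, and 45.9% of the genes had the lower range in the last 5. The quartiles of the differences were -0.333 and 0.380 log2. The median loss of over 0.2 log2 that such drift was set to show was not seen among these genes. They were called by a cosine of constant size over all 10 libraries, so genes whose cycle flattened were less likely to enter. A loss in such genes, or a smaller loss, stays open.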
